A study of Homo sapiens with 8 samples.

How the data were processed

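RNA was measured in 8 libraries of MCF7 cells, an estrogen receptor-positive breast cancer line. Per the labels' protocols, cells were transfected for 72 h with siRNA at 20 nM (written "20nm" there) using HiPerfect, total RNA was isolated on columns, and polyA-selected libraries were made. The 4 groups of 2 libraries were siControl, siCHRNA5, siTP53 and siCHRNA5+siTP53. The labels do not say how the dose was divided in the double treatment, how many siRNA sequences were used against each gene, or whether the 2 libraries of a group came from separate cultures. The p-values therefore measure the spread between these libraries only.

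The values deposited by the authors are raw read counts per gene symbol, per the labels, which name the column of each library in a table of raw counts. Per the submitters' processing notes, FastQC, STAR and HTSeq were used with the genome build hg19, without versions or roles. The gene annotation and the strand setting of the counting are not given in the sources used here. The table held 15628 gene symbols as whole numbers, with no entry that named no gene. The lowest total of a gene over the 8 libraries was 19 reads, and 2034 genes had totals up to 100, so genes with very few reads had been left out before deposit by a rule that is not stated. Of the symbols, 15398 matched a RefSeq gene by name, 13473 of them protein coding. The reference annotation at hand was GENCODE v29 on another genome build (GRCh38), so it served only for names, neighbouring and overlapping genes and 3' UTR sequences, and no coordinates are given.

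Library totals lay between 36 M and 43.8 M reads. Counts were analysed in R 4.3.3 with edgeR 4.0.16, with limma 3.58.1 and DESeq2 1.42.0 as further tools. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. filterByExpr kept 14501 genes and removed 1127. The libraries were scaled by TMM, all 8 entered one fit with a term per group, and each comparison was tested two-sided with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment at an adjusted p under 0.05. The fit had 4 residual degrees of freedom and 5.02 prior degrees of freedom. The standard error (SE) of a log2 fold change is its size divided by the square root of F. Levels are CPM (counts scaled by the TMM-adjusted library size), with the SD over the 2 libraries of a group.

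The comparisons were siCHRNA5, siTP53 and siCHRNA5+siTP53 each against siControl, siCHRNA5+siTP53 against each single siRNA, and the interaction, which is the fold change of siCHRNA5+siTP53 over siTP53 minus that of siCHRNA5 over siControl on the log2 scale. Genes are named by a rule. CHRNA5, TP53 and the cluster neighbours CHRNA3, CHRNB4, PSMA4 and IREB2 are always given. In each comparison the 6 largest rises and 6 largest falls are named among genes past the threshold with a mean of at least 5 CPM and both libraries of one group above both of the other. For the interaction the separation of libraries was not required. From each core list the 2 members with the smallest adjusted p, and from each other list 1, are added, with up to 2 of the most highly expressed members that did not pass as examples. Other genes are named only where the text says so.

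The 22 gene lists were written from general knowledge. The 9 core lists are p53 targets, G1/S replication, G2/M mitosis, estrogen response, apoptosis, DNA repair and checkpoint, nicotinic receptors, the unfolded protein and integrated stress response, and the interferon response. The others are NF-kB inflammation, cholesterol synthesis, hypoxia and glycolysis, mesenchymal genes, luminal epithelial genes, lysosome and autophagy, immediate early genes, mitochondrially encoded genes, replication-dependent histones, and markers of basal epithelial cells, fibroblasts, leukocytes and endothelial cells. Lists with at least 3 tested members (21 of them) were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance, were run beside it. Members past the threshold were counted over all genes tested and also after adjustment over the list alone. The tests of the comparisons and lists, the gene lists, the naming rule and most alternatives were fixed before the data were examined. The scan of 3' UTR heptamers was not part of that plan. The explanations weighed below concern patterns seen in these data.

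Overlaps and correlations of fold changes were set beside the overlap of independent lists and, for comparisons with the same control libraries, beside 20 simulations of unchanged groups. A scan related the log2 fold changes of 9643 genes with at least 5 CPM and a GENCODE 3' UTR of at least 20 bases to the presence of each of 16158 heptamers, each found in at least 50 genes. Each heptamer had its own linear model, with log2 3' UTR length, GC content, their squares and their product as covariates and fold changes limited to 3 log2 units either way. Of 9749 protein-coding genes at that level, 9532 (97.8%) had a 3' UTR sequence.

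The main test was tested on simulated data with the means and library sizes of these genes for the comparison of siCHRNA5 with siControl. Over 10 simulations of 14232 genes it found 55% of planted log2 changes of 1 and 79.4% of those of 2, and 6.61% of its calls were false. Each gene had the same spread in all libraries, although the siCHRNA5 libraries lay further apart (SD of the log2 difference 0.524, against 0.151 to 0.247 in other groups). These rates may therefore not hold for the real siCHRNA5 libraries. Camera found the planted change of 0.5 in a list of 30 genes in 10 of 10 simulations and no unchanged list. The simulated genes varied independently, whereas the estimated correlation with siCHRNA5 was 0.151 for p53 targets and 0.478 for G1/S genes. The rate of false calls in lists of correlated genes was therefore not tested. The heptamer scan ranked 20 of 20 planted heptamers first, and its lowest t without an effect was -4.87.

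The alternatives were other scalings (median of ratios, library totals), DESeq2, limma-voom, no filter or a filter at 5 CPM, the replicate number as a block, only the groups compared, an adjusted p under 0.01, and leaving out each library in turn. Per-library quality weights and lists without members that hold a leading heptamer were added after seeing the data. With 2 libraries per group, no test for single outlying libraries and no regrouping of samples was made. Fibroblast markers had too few tested members for a list test. No file of the series was left out.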

Results

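Gene expression was measured by polyA RNA sequencing in MCF7 cells, a luminal, estrogen receptor-positive breast cancer line, 72 h after transfection with siRNA. CHRNA5 encodes the alpha5 subunit of nicotinic acetylcholine receptors, and TP53 encodes the transcription factor p53. The 4 groups, siControl, siCHRNA5, siTP53 and siCHRNA5+siTP53, had 2 libraries each. Total counts were 43.8 M and 39.5 M reads for siControl, 39.1 M and 37.3 M for siCHRNA5, 41.3 M and 37.6 M for siTP53, and 36 M and 39.3 M for siCHRNA5+siTP53. Log2 fold changes are given with their SE and an adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and list tests are from camera. The series asks which responses to CHRNA5 silencing depend on TP53.

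The siCHRNA5 libraries differed from each other more than the libraries of the other groups. Among 10162 genes with at least 5 CPM, the SD of the log2 difference between the libraries of a group was 0.524 for siCHRNA5, 0.208 for siControl, 0.247 for siTP53 and 0.151 for siCHRNA5+siTP53. In siCHRNA5, 568 genes lay over 2-fold apart, against at most 23 in another group. In siCHRNA5 replicate 1, cholesterol synthesis genes (median log2 difference 0.852), immediate early genes (0.806), lysosome genes (0.562), replication histones (0.467) and NF-kB genes (0.287) lay above replicate 2. G2/M genes (-0.594), mitochondrially encoded genes (-0.53), G1/S genes (-0.476), interferon response genes (-0.426) and DNA repair genes (-0.302) lay below it, and p53 targets were 0.192 higher. Because all groups shared one estimate of spread, this pair also affects how many genes pass in comparisons that do not contain it.

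CHRNA5 was low in every library that received its siRNA, and TP53 in every library that received the TP53 siRNA. CHRNA5 stood at 13.6 and 11.3 CPM in siControl, 16.8 and 15.5 CPM in siTP53, 0.29 and 1.28 CPM in siCHRNA5, and 1.19 and 2.63 CPM in siCHRNA5+siTP53. It fell by 3.98 ± 0.555 on the log2 scale with siCHRNA5 (adjusted p = 0.00306) and by 2.70 ± 0.509 with siCHRNA5+siTP53 against siControl (adjusted p = 0.00586, but 0.0603 without siCHRNA5+siTP53 replicate 1). An antisense gene covers 23.0% of its exonic bases, and without a stated strand setting reads of the pair could not be told apart. TP53 stood at 134.7 and 133.2 CPM in siControl, 110.1 and 138.9 CPM in siCHRNA5, 21.8 and 19.8 CPM in siTP53, and 16.0 and 16.2 CPM in siCHRNA5+siTP53. It fell by 2.69 ± 0.144 with siTP53 (adjusted p = 0.000117) and fell by 3.06 ± 0.147 with both siRNAs (adjusted p = 4.43e-05). Its change with siCHRNA5 (-0.11 ± 0.134, adjusted p = 0.651) did not pass and was 0.05 without siCHRNA5 replicate 1. Of the genes beside CHRNA5, IREB2, which encodes an iron-regulatory protein, rose by 0.43 ± 0.112 with siCHRNA5 (adjusted p = 0.0354) and by 0.38 with both siRNAs against siControl (adjusted p = 0.0337). The receptor subunit genes CHRNA3 (-1.57, adjusted p = 0.213) and CHRNB4 (-0.12, adjusted p = 0.917) and the proteasome gene PSMA4 (0.14, adjusted p = 0.613) did not pass there or in any other comparison.

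**Figure D1:**
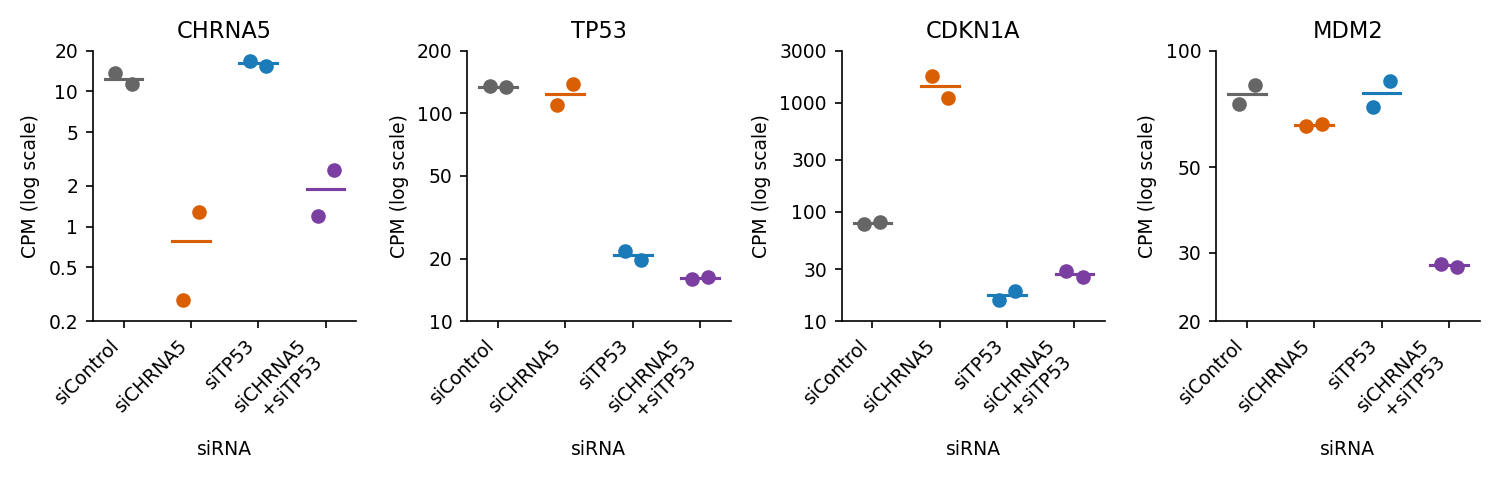
CPM on a log axis for CHRNA5, TP53, CDKN1A and MDM2 in the 4 siRNA groups; each point is a library and each line a group mean of 2 libraries. CDKN1A stood at 1754 and 1109 CPM in siCHRNA5 and at most 80.9 CPM in the other groups, and MDM2 was at 28.1 and 27.6 CPM in siCHRNA5+siTP53 and at least 63.9 CPM elsewhere.

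The comparison of siCHRNA5 with siControl asks what CHRNA5 siRNA does while TP53 is intact. The cell cycle inhibitor gene CDKN1A rose by 4.17 ± 0.23 (adjusted p = 9.98e-05), from 79.4 ± 2.12 to 1430 ± 456 CPM (mean and SD, n = 2). The death receptor gene FAS rose by 3.27 ± 0.246 (adjusted p = 0.000343) and the cotransporter gene SLC12A4 by 3.15 ± 0.284 (adjusted p = 0.000554). Large rises were also those of the heme oxygenase gene HMOX1 (4.80 ± 1.0, adjusted p = 0.0148), the stress cytokine gene GDF15 (4.34 ± 0.952, adjusted p = 0.018) and the reductase gene AKR1C1 (3.95 ± 1.05, adjusted p = 0.0372). These 3 rested mostly on siCHRNA5 replicate 1, without which they were 1.80, 1.46 and 0.45, the last with an adjusted p of 0.16. HMOX1 was at 2099 and 140 CPM in siCHRNA5 replicates 1 and 2 and at a mean of 40.2 CPM in siControl, and GDF15 was at 1682 and 122 CPM against 44.5 CPM. AKR1C1, which shares sequence with close paralogs and holds a CHRNA5 siRNA heptamer (see the 3' UTR scan), was at 102 and 4.72 CPM against 3.46 CPM. Besides CHRNA5, the transcription factor gene FOXI1 (-4.17 ± 0.44, adjusted p = 0.001) and the reductase gene DHRS2 (-3.77 ± 0.3, adjusted p = 0.000362) fell most. They were followed by the actin-binding protein gene TWF1 (-2.94 ± 0.122, adjusted p = 2.39e-05), the thioesterase gene LYPLA1 (-2.90 ± 0.14, adjusted p = 4.65e-05) and the methyltransferase gene METTL7A (-2.78 ± 0.236, adjusted p = 0.000489). The 3' UTRs of TWF1 and LYPLA1 hold a CHRNA5 siRNA heptamer.

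In all, 2134 of 14501 genes (14.7%) passed in siCHRNA5 against siControl by edgeR's quasi-likelihood test, 900 higher and 1234 lower, of which 285 and 504 changed at least 2-fold. The count was 477 without siControl replicate 1, 507 without siControl replicate 2, 3574 without siCHRNA5 replicate 1, 4932 without siCHRNA5 replicate 2, and 1225 and 1222 without siCHRNA5+siTP53 replicate 1 or 2. Only 342 genes, all among the 2134, passed when only the compared groups entered the fit. HMOX1 and GDF15 did not pass without siControl replicate 1 (adjusted p = 0.114 and 0.151) or 2 (0.143 for both). AKR1C1 did not pass without any one library other than siCHRNA5 replicate 2 (adjusted p = 0.0632 to 0.227), nor with limma-voom (0.278).

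Of 40 tested p53 targets, 26 rose with siCHRNA5 and 1 fell, 13 did not pass, and 29 rose and 1 fell when adjusted over the list alone. Their median log2 fold change was 1.28 (camera adjusted p = 2.23e-20, adjusted p = 0.27 with an estimated correlation), and 1.11 without siCHRNA5 replicate 1. The growth factor gene KITLG was the one that fell (-0.73, adjusted p = 0.0101; singled out after its value was seen). The phosphatase gene PPM1D (0.57, adjusted p = 0.0667) and CMBL (0.05, adjusted p = 0.795) did not pass, and neither did MDM2, whose protein degrades p53 (-0.26, adjusted p = 0.194; singled out after its value was seen). The 3' UTR of MDM2 holds heptamers of both siRNAs.

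Of 39 G1/S replication genes, 32 fell and 0 rose with siCHRNA5 by edgeR's test (DESeq2 0 as well), and 37 fell when adjusted over the list alone. Their median was -1.13 (camera adjusted p = 1.8e-25, adjusted p = 0.376 with an estimated correlation). The helicase subunit genes MCM5 (-1.49 ± 0.126, adjusted p = 0.000489) and MCM7 (-1.14 ± 0.108, adjusted p = 0.000653) fell. GINS1 (-0.79, adjusted p = 0.0609) and DHFR (-0.71, adjusted p = 0.176) did not pass. Of 40 G2/M genes, 25 fell and 0 rose, and 36 fell when adjusted over the list alone. The median was -0.75 (camera adjusted p = 1.23e-16, adjusted p = 0.376 with an estimated correlation), or -0.49 without siCHRNA5 replicate 1. The mitotic kinase gene AURKA (-0.94 ± 0.109, adjusted p = 0.0014) and the spindle gene PRC1 (-0.75 ± 0.105, adjusted p = 0.00314) fell, PRC1 with 65.2% of its exonic bases shared with another gene on its strand. CCNB1 (-0.27, adjusted p = 0.12) and ECT2 (-0.28, adjusted p = 0.213) did not pass. Of 39 DNA repair and checkpoint genes, 21 fell and 1 rose, and 27 fell and 1 rose when adjusted over the list alone. The median was -0.658 (camera adjusted p = 9.74e-11, adjusted p = 0.376 with an estimated correlation). FANCD2 (-1.55 ± 0.124, adjusted p = 0.000362), of the Fanconi repair pathway, and the exonuclease gene EXO1 (-1.54 ± 0.18, adjusted p = 0.00144) fell, and H2AX (-0.50, adjusted p = 0.122) and NBN (-0.18, adjusted p = 0.68) did not pass. The G1/S, G2/M and repair genes were also among those lower in siCHRNA5 replicate 1 than in replicate 2.

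Immediate early genes, which respond within minutes to growth factors and handling, rose with siCHRNA5, with 9 up and 1 down of 24 (12 and 1 adjusted over the list alone). Their median was 0.899 (camera adjusted p = 3.35e-05, adjusted p = 0.582 with an estimated correlation) and 0.399 without siCHRNA5 replicate 1, and 17 rose without siCHRNA5 replicate 2. By fry the list did not pass (adjusted p = 0.119). EGR1 rose by 2.45 ± 0.331 (adjusted p = 0.00266). Lysosome and autophagy genes rose by camera but not by fry (adjusted p = 0.247), with 6 up and 0 down of 29 (8 and 0 adjusted over the list alone). Their median was 0.295 (camera adjusted p = 0.00941, adjusted p = 0.673 with an estimated correlation) and 0.444 without siCHRNA5 replicate 2, where 16 rose. Without siCHRNA5 replicate 1 it was -0.0468 and the list did not pass (adjusted p = 0.895). WIPI1, an autophagy gene 28.5% of whose exonic bases overlap the antisense gene ARSG, rose by 1.02 ± 0.169 (adjusted p = 0.00597, but 0.0712 without siControl replicate 1).

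Estrogen response genes did not pass as a list with siCHRNA5 (3 up and 5 down of 36, 4 and 5 adjusted over the list alone, camera adjusted p = 0.457). The counts were 5 and 10 without siCHRNA5 replicate 1 and 11 and 12 without siCHRNA5 replicate 2. The progesterone receptor gene PGR rose by 2.18 ± 0.242 (adjusted p = 0.00115) and MYB fell by 0.82 ± 0.116 (adjusted p = 0.00324). SLC39A6 (0.00, adjusted p = 0.987) and the secreted factor gene TFF1 (-0.37, adjusted p = 0.392) did not pass. Apoptosis genes went both ways (5 up and 3 down of 34, 5 and 5 adjusted over the list alone, camera adjusted p = 0.361), with 5 and 5 without siCHRNA5 replicate 1 and 10 and 6 without siCHRNA5 replicate 2. FAS and the survival gene MCL1 (0.73 ± 0.109, adjusted p = 0.00385) rose, and CYCS (0.07, adjusted p = 0.732) and BCL2L1 (-0.27, adjusted p = 0.185) did not pass. The unfolded protein and integrated stress response did not pass as a list (5 up and 3 down of 30, 6 and 3 adjusted over the list alone, camera adjusted p = 0.185). It had 5 up and 5 down without siCHRNA5 replicate 1 and 13 up and 4 down without siCHRNA5 replicate 2. Of its members SESN2, which p53 also activates, rose by 2.00 ± 0.165 (adjusted p = 0.00045), and the serine synthesis gene PHGDH fell by 1.22 ± 0.151 (adjusted p = 0.00185). Nor did the interferon response (1 up and 4 down of 27, 3 and 4 adjusted over the list alone, camera adjusted p = 0.114), with 5 and 5 without siCHRNA5 replicate 1 and 1 and 10 without siCHRNA5 replicate 2. OAS3 fell by 1.74 ± 0.254 (adjusted p = 0.0036), and IRF7 rose by 1.31 ± 0.214 (adjusted p = 0.00562, but 0.0694 without siControl replicate 1). From other lists, the cytokine gene LIF (2.82 ± 0.343, adjusted p = 0.0017) and the integrin gene ITGA5 (2.58 ± 0.264, adjusted p = 0.000929) rose. PFKP of glycolysis (-1.14 ± 0.109, adjusted p = 0.000733) and the mucin gene MUC1 (-1.31 ± 0.17, adjusted p = 0.00223), which holds a CHRNA5 siRNA heptamer, fell. Cholesterol synthesis genes did not pass as a list (1 up and 0 down of 23, camera adjusted p = 0.675). Their median was 0.124, or -0.37 without siCHRNA5 replicate 1. Of them SC5D rose by 1.46 ± 0.382 (adjusted p = 0.0344), or 0.51 without siCHRNA5 replicate 1. It did not pass without siControl replicate 1 or 2, siTP53 replicate 1 or 2, or siCHRNA5+siTP53 replicate 1 or 2 (adjusted p = 0.0621 to 0.202), nor with limma-voom (0.0647).

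The comparison of siCHRNA5+siTP53 with siTP53 asks what CHRNA5 siRNA does once TP53 is silenced, and shares no library with the former. The falls were led by CHRNA5 (-3.07 ± 0.514, adjusted p = 0.0373), DHRS2 (-3.05 ± 0.279, adjusted p = 0.00301) and METTL7A (-3.00 ± 0.25, adjusted p = 0.00272). Next came the muscle membrane gene SGCG (-2.01 ± 0.301, adjusted p = 0.0252), LYPLA1 (-1.91 ± 0.135, adjusted p = 0.00158) and the calmodulin-like gene CALML5 (-1.79 ± 0.23, adjusted p = 0.0135). The tight junction gene CLDN1 (2.05 ± 0.307, adjusted p = 0.0252) and ITGA5 (1.91 ± 0.247, adjusted p = 0.0136) rose most. Smaller rises were those of the deubiquitinase gene USP2 (1.61 ± 0.276, adjusted p = 0.0419), ARID3B (1.44 ± 0.24, adjusted p = 0.0373), HS6ST2 (1.22 ± 0.152, adjusted p = 0.0113) and NT5C2 (1.19 ± 0.169, adjusted p = 0.0196). Of the exonic bases of NT5C2, 54.1% overlap the antisense gene CNNM2. MDM2 fell by 1.48 ± 0.128 (adjusted p = 0.00293), from 77.7 ± 8.54 to 27.9 CPM. CDKN1A (0.65 ± 0.21, adjusted p = 0.231) and GDF15 (adjusted p = 0.245) did not pass, and TP53 (-0.37 ± 0.139, adjusted p = 0.298) passed without siCHRNA5 replicate 1 (0.0398) or 2 (0.0408). CALML5, USP2, ARID3B, HS6ST2 and NT5C2 hold a TP53 siRNA heptamer.

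In siCHRNA5+siTP53 against siTP53, 98 genes passed by edgeR's test (24 up, 74 down; 7 and 48 at least 2-fold), and 1998 had an unadjusted p under 0.05. The count was 481 with DESeq2 and 107 with limma-voom, 1305 when only these 2 groups entered the fit, and 1457 without siCHRNA5 replicate 1 or without siCHRNA5 replicate 2. It was 30 without siControl replicate 1 or without siControl replicate 2, and 5 and 17 without siTP53 replicate 1 or 2. Without siCHRNA5+siTP53 replicate 1 or 2 it was 0 by edgeR, with 864 and 1030 genes at an unadjusted p under 0.05. So none of the 13 genes named as changed, MDM2 included, passed with each library left out in turn. CHRNA5 and CLDN1 (adjusted p = 0.13 to 0.441 and 0.0885 to 0.326), ITGA5 (0.0546 to 0.251), USP2, ARID3B, NT5C2 and SGCG (highest 0.464) did not pass without any one siControl, siTP53 or siCHRNA5+siTP53 library. HS6ST2 and CALML5 (highest 0.251) did not pass without any one siTP53 or siCHRNA5+siTP53 library, DHRS2 (0.094) without siTP53 replicate 1 or either siCHRNA5+siTP53 library, and METTL7A, LYPLA1 and MDM2 (highest 0.122) without siCHRNA5+siTP53 replicate 1 or 2. With limma-voom, SGCG (0.218) and ARID3B (0.0586) did not pass.

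With TP53 silenced, CHRNA5 siRNA left p53 targets with 0 rises and 1 fall (MDM2) of 40 by edgeR's test, and the same when adjusted over the list alone. There were 3 rises and 3 falls without siCHRNA5 replicate 1 or without siCHRNA5 replicate 2, and 4 rises and 2 falls with quality weights. Their median was -0.0824 and their mean 0.129, with camera pointing up (adjusted p = 0.971) and fry down. Single members ranged from -1.48 to 2.66. The median of the list was 0.0489 without siCHRNA5+siTP53 replicate 2 and -0.00121 without siTP53 replicate 1. By fry no list passed in this comparison (adjusted p = 0.464 for G1/S genes and histones, 0.34 for interferon response and mesenchymal genes). G1/S genes fell as a list by camera (median -0.23, camera adjusted p = 2.58e-07, adjusted p = 0.769 with an estimated correlation). Over all genes 0 members passed by edgeR and 3 by DESeq2, and 3 fell adjusted over the list alone, but 11 fell and 0 rose without siCHRNA5 replicate 1 or without siCHRNA5 replicate 2. MCM7 (-0.22, adjusted p = 0.395) and RRM2 (-0.02, adjusted p = 0.99) did not pass. G2/M genes (median -0.0739, camera adjusted p = 0.933) and DNA repair genes (median -0.174, camera adjusted p = 0.075) did not pass as lists. Some repair genes fell without siCHRNA5 replicate 1 or without siCHRNA5 replicate 2. TOP2A (0.31, adjusted p = 0.529) did not pass. Interferon response genes fell (median -0.428, camera adjusted p = 0.00639, adjusted p = 0.769 with an estimated correlation). Of them 0 passed over all genes by edgeR, 2 by DESeq2, and 1 adjusted over the list alone, but 6 and 5 fell without siCHRNA5 replicate 1 or 2. Mesenchymal genes rose (median 0.106, camera adjusted p = 0.04, adjusted p = 0.769 with an estimated correlation), with 1 up over all genes (3 by DESeq2, 4 without siCHRNA5 replicate 1 or 2) and 4 adjusted over the list alone. The list did not pass without siTP53 replicate 1 (0.0901) or 2 (0.0722), nor over members without a siRNA heptamer (0.225). Replication histones rose (median 0.357, camera adjusted p = 0.0455, adjusted p = 0.769 with an estimated correlation) as a list, though 0 members passed over all genes by edgeR. By DESeq2 1 rose, adjusted over the list alone 1 rose, and without siCHRNA5 replicate 1 or without siCHRNA5 replicate 2 2 rose and 1 fell. The list did not pass without siTP53 replicate 2 (0.395) or siCHRNA5+siTP53 replicate 2 (0.0871).

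Across genes, the fold changes of CHRNA5 siRNA without and with TP53 siRNA correlated at r = 0.374 (14501 genes, which are not independent replicates). With 1 library per group, the 16 combinations gave 0.234 to 0.384, and leaving out siCHRNA5 replicate 1 or siCHRNA5+siTP53 replicate 1 gave 0.248 and 0.224. With the filter at 5 CPM r was 0.617. ITGA5 was among 22 genes that rose in both, where independent lists of these sizes would share 1.49. CHRNA5, DHRS2, METTL7A and LYPLA1 were among 67 that fell in both, where independent lists would share 6.3. No call went in opposite directions, and 87.4% of the 2134 genes called without TP53 siRNA had the same sign with it, with a median ratio of the log2 fold changes of 0.362.

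**Figure D2:**
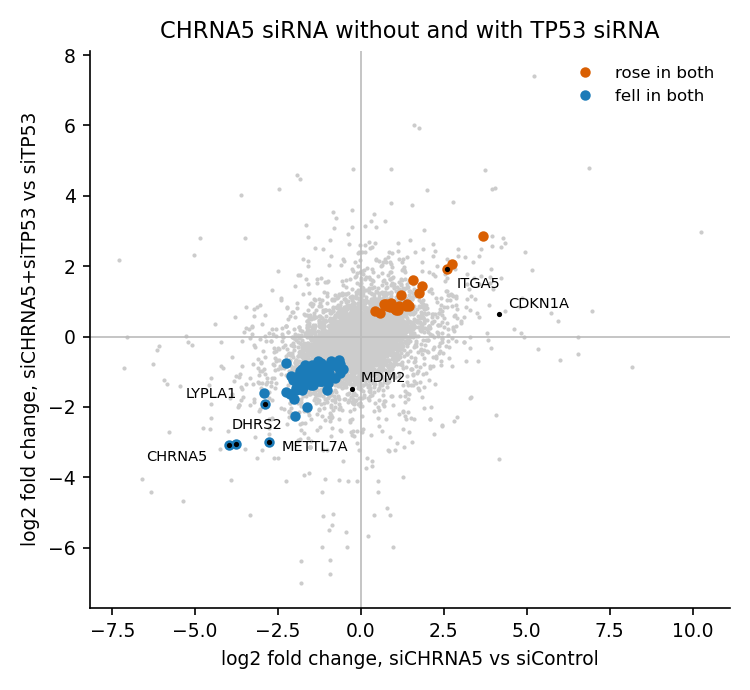
Log2 fold change of each of 14501 genes with CHRNA5 siRNA alone (horizontal) and on top of TP53 siRNA (vertical); orange points are the 22 genes that rose and blue points the 67 genes that fell in both. CDKN1A lies at 4.17 and 0.65 and MDM2 at -0.26 and -1.48.

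The interaction tests the difference between those 2 responses directly. By edgeR's test 2 genes passed, CDKN1A (-3.53 ± 0.299, adjusted p = 0.0125) and RPS27L (-2.06 ± 0.214, adjusted p = 0.0347), both p53 targets, and 1660 genes had an unadjusted p under 0.05. RPS27L, a paralog of RPS27 whose reads the counting could have split, was at 55.0 ± 0.528 CPM in siControl, 215 ± 15.7 CPM in siCHRNA5, 27.2 ± 4.51 CPM in siTP53 and 25.4 CPM in siCHRNA5+siTP53. CDKN1A was at 79.4, 1430, 17.3 and 27.0 CPM in the same order. DESeq2 called 351 genes, limma-voom 2 and library totals 12. Without any one siControl, siTP53 or siCHRNA5+siTP53 library no gene passed by edgeR, and the adjusted p of both genes was 0.119 to 0.303. Without siCHRNA5 replicate 1 or 2, 963 and 1864 genes passed. MDM2 (-1.22, adjusted p = 0.0701), MCM7 (0.92 ± 0.151, adjusted p = 0.0849), GDF15 (-1.68, adjusted p = 0.647), RRM2 (1.06, adjusted p = 0.303) and TOP2A (1.09, adjusted p = 0.181) did not pass.

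As lists, p53 targets had a negative interaction (median -1.24, camera adjusted p = 1.47e-27, adjusted p = 0.154 with an estimated correlation, fry adjusted p = 0.0358). Over all genes 2 members had one by edgeR, 23 by DESeq2 and 7 with library totals, and 27 when adjusted over the list alone. Without siCHRNA5 replicate 1 or 2 it was 22 and 29, and without any one other library 0. G1/S genes (median 0.876, camera adjusted p = 2.27e-28), G2/M genes (0.704, 5.99e-23, and a median of 1.08 without siCHRNA5 replicate 2) and DNA repair genes (0.53, 1.56e-12) had positive interactions, each with an adjusted p = 0.309 with an estimated correlation. By fry none of these lists passed (adjusted p = 0.0866 for G1/S genes and 0.0973 for G2/M and DNA repair genes). Over all genes 0 of their members passed by edgeR, DESeq2 called 21, 9 and 8, and 30, 23 and 12 passed adjusted over the list alone. These were 25, 13 and 11 without siCHRNA5 replicate 1, and without siCHRNA5 replicate 2 they were 34, 37 and 22. Immediate early genes (median -0.766, camera adjusted p = 0.000363) and lysosome genes (-0.325, 0.000856) had negative interactions, both with an adjusted p = 0.543 with an estimated correlation, and without siCHRNA5 replicate 1 neither passed (0.386 and 0.902, medians -0.164 and -0.0495). Hypoxia and glycolysis genes had a small positive interaction (median 0.163, camera adjusted p = 0.0293, adjusted p = 0.476 with an estimated correlation). It did not pass without siControl replicate 1 (0.0873), siCHRNA5 replicate 2 (0.0572), siTP53 replicate 2 (0.175) or siCHRNA5+siTP53 replicate 2 (0.153), nor over members without a siRNA heptamer (0.317). The number adjusted over the list alone was 2 below 0 for immediate early genes, 0 for lysosome genes and 2 above 0 for hypoxia genes. Over all genes 0 members of these 3 lists passed by edgeR, and DESeq2 called 2, 0 and 2. By fry the immediate early and lysosome lists (adjusted p = 0.479 for both) and the hypoxia list (0.19) did not pass. The numbers above and below 0 without siCHRNA5 replicate 1 were 2 and 2, 2 and 0, and 3 and 0, and without siCHRNA5 replicate 2 they were 1 and 12, 0 and 10, and 4 and 3.

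**Figure D3:**
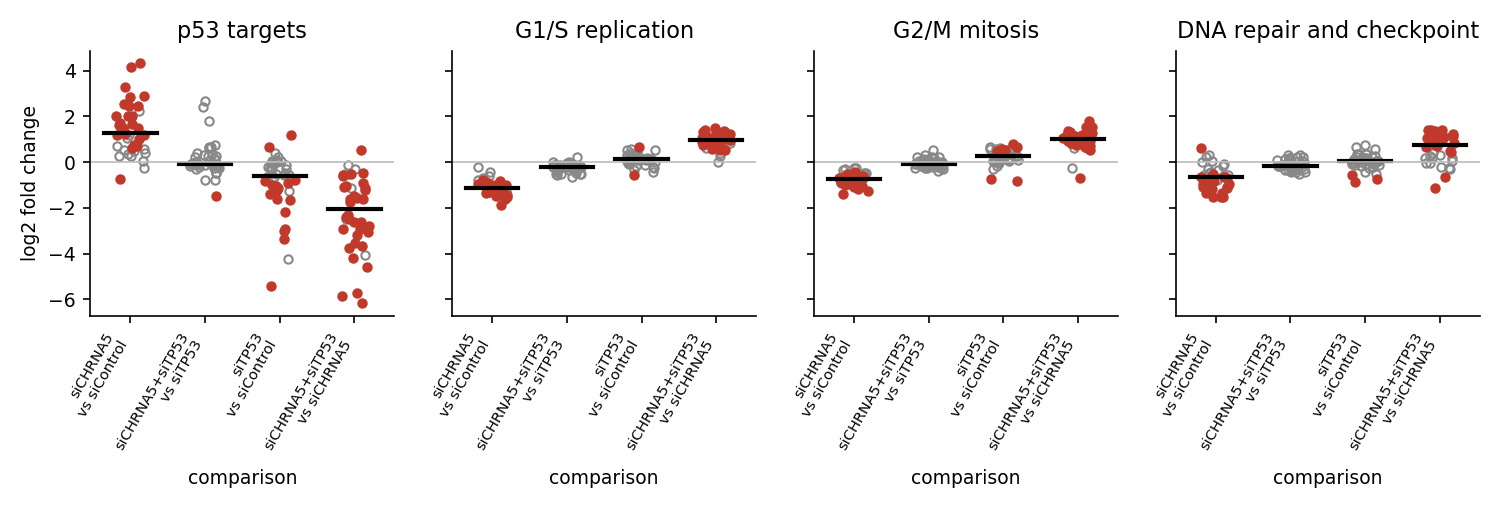
Log2 fold change of each tested member of 4 gene lists in 4 comparisons; red points passed the adjusted threshold, open points did not, and bars are medians. The median of the p53 targets was 1.28, -0.0824, -0.602 and -2.04 from left to right.

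The comparison of siTP53 with siControl asks what silencing TP53 does by itself. The largest falls were those of the transporter gene SLC5A8 (-5.46 ± 0.51, adjusted p = 0.000809), SGCG (-4.51 ± 0.236, adjusted p = 0.000117) and IFITM10 (-3.33 ± 0.324, adjusted p = 0.000897). The protease gene TMPRSS4 (-3.18 ± 0.717, adjusted p = 0.0213), the adhesion gene NRXN3 (-3.06 ± 0.269, adjusted p = 0.000717) and the protocadherin gene PCDH19 (-3.06 ± 0.497, adjusted p = 0.00639) came next, and these 3 hold a TP53 siRNA heptamer. The growth factor gene TGFB2 (4.24 ± 0.693, adjusted p = 0.00649), the secretory protein gene AGR2 (2.96 ± 0.392, adjusted p = 0.0028) and ANXA3 (2.75 ± 0.448, adjusted p = 0.00645) rose most. LRRC26 (2.64 ± 0.299, adjusted p = 0.00164), MACC1 (2.62 ± 0.205, adjusted p = 0.000446) and GALNT12 (2.60 ± 0.505, adjusted p = 0.0122) came next. IFITM10, LRRC26 and TGFB2 share 28.7%, 27.5% and 27.1% of their exonic bases with another gene on the same strand. In all 2155 genes (14.9%) passed, 929 higher and 1226 lower, or 516 and 1632 with library totals alone, which moved the median of all genes by -0.103. The count was 434 and 299 without siControl replicate 1 or 2, 393 and 680 without siTP53 replicate 1 or 2, 1104 and 1097 without siCHRNA5+siTP53 replicate 1 or 2, and 5213 and 5208 without siCHRNA5 replicate 1 or 2. Without siControl replicate 2, TGFB2 (adjusted p = 0.061), ANXA3, GALNT12, TMPRSS4 and PCDH19 did not pass. The last 4 also did not pass without siTP53 replicate 1, nor did ANXA3, GALNT12 and TMPRSS4 without siControl replicate 1 or GALNT12 and TMPRSS4 without siTP53 replicate 2 (highest adjusted p = 0.119).

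Of 40 p53 targets, 15 fell and 2 rose with siTP53 by edgeR's test, and 19 and 3 adjusted over the list alone. The falls numbered 8 without siControl replicate 2 or without siTP53 replicate 1, and 24 without siCHRNA5 replicate 1 or without siCHRNA5 replicate 2. Their median was -0.602 (camera adjusted p = 5.43e-05, adjusted p = 0.723 with an estimated correlation), and by fry the list did not pass (adjusted p = 0.0644). BTG2, an antiproliferative gene that holds a TP53 siRNA heptamer, fell by 2.91 ± 0.223 (adjusted p = 0.000446) and CDKN1A by 2.20 ± 0.215 (adjusted p = 0.000897). GDF15 (-1.27, adjusted p = 0.349) and PPM1D (-0.25, adjusted p = 0.379) did not pass. G2/M genes rose as a list by camera but not by fry (adjusted p = 0.379), with 5 up and 2 down of 40 (8 and 2 adjusted over the list alone). Their median was 0.265 (camera adjusted p = 0.00191, adjusted p = 0.913 with an estimated correlation), or 0.161 with library totals, where 3 rose. Without siCHRNA5 replicate 1 or without siCHRNA5 replicate 2, 18 rose. CDC20 rose by 0.65 ± 0.102 (adjusted p = 0.0054, but 0.0671 without siControl replicate 2). G1/S genes did not pass as a list (1 up and 1 down of 39, 0 adjusted over the list alone, camera adjusted p = 0.141). More members passed, most of them up, without siCHRNA5 replicate 1 or without siCHRNA5 replicate 2. MCM7 (0.12, adjusted p = 0.494), RRM2 (0.32, adjusted p = 0.42) and TOP2A (0.26, adjusted p = 0.4) did not pass.

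Stress response genes rose with siTP53, with 7 up and 2 down of 30 (12 and 3 adjusted over the list alone). Their median was 0.399 (camera adjusted p = 0.00191, adjusted p = 0.723 with an estimated correlation). The secretory pathway regulator XBP1 rose by 1.19 ± 0.133 (adjusted p = 0.00159), and the amino acid transporter gene SLC3A2 fell by 0.97 ± 0.142 (adjusted p = 0.00429, but 0.0504 without siControl replicate 2). NF-kB inflammation genes rose, with 3 up and 1 down of 16 (6 and 1 adjusted over the list alone). Their median was 0.448 (camera adjusted p = 0.031, adjusted p = 0.774 with an estimated correlation), and the receptor gene IL6ST rose by 1.10 ± 0.13 (adjusted p = 0.00193). Replication histones rose, with 3 up and 0 down of 14 (4 and 0 adjusted over the list alone). Their median was 0.966 (camera adjusted p = 0.0012, adjusted p = 0.723 with an estimated correlation), and H2BC11 rose by 2.00 ± 0.28 (adjusted p = 0.0035, but 0.0527 without siControl replicate 2). Without siCHRNA5 replicate 1 or without siCHRNA5 replicate 2, 16 stress response genes, 8 NF-kB genes and 9 histones rose. Reads of histone genes can be split between near-identical copies and most of their RNA lacks polyA, so these values are uncertain. By fry, none of the stress response, NF-kB and histone lists passed (adjusted p = 0.0644, 0.201 and 0.0644).

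In lists that did not pass with siTP53, the survival gene BCL2 (-1.49 ± 0.162, adjusted p = 0.00134) and FAS (-1.68 ± 0.267, adjusted p = 0.00577) fell. They belong to the apoptosis genes, with 2 up and 4 down of 34 (3 and 5 adjusted over the list alone, camera adjusted p = 0.926), or 7 and 9 without siCHRNA5 replicate 1 or without siCHRNA5 replicate 2. The lysosomal glucosidase gene GAA (-0.86 ± 0.11, adjusted p = 0.0024) and ENO2 of glycolysis (-1.92 ± 0.303, adjusted p = 0.00559) fell, and the matrix protein gene CCN1 (1.26 ± 0.154, adjusted p = 0.0022) rose. FAS passed neither without siControl replicate 2 (0.0571) nor without siTP53 replicate 1 (0.0646). ENO2 did not pass without siControl replicate 2 or siTP53 replicate 1 or 2 (highest 0.0598). Estrogen response genes did not pass as a list (3 up and 5 down of 36, the same adjusted over the list alone, camera adjusted p = 0.652), though more members passed in those fits. The transporter gene SLC7A2, which holds heptamers of both siRNAs, fell by 0.98 ± 0.155 (adjusted p = 0.00572, but 0.0707 without siTP53 replicate 1). DNA repair genes did not either (1 up and 3 down of 39, 0 and 1 adjusted over the list alone, camera adjusted p = 0.56), with 8 and 4 in those fits. RAD17, which holds a TP53 siRNA heptamer, fell by 0.87 ± 0.136 (adjusted p = 0.00536). Its value was -0.79 without siControl replicate 2 and -0.77 without siTP53 replicate 2, where it did not pass (adjusted p = 0.0663 and 0.0519). TYMS (58.2% overlapped by the antisense gene ENOSF1), E2F2, ATM, IRF7, CENPA and PARP9 passed with all libraries but not without siControl replicate 1 or 2 or siTP53 replicate 1 or 2 (adjusted p = 0.0505 to 0.24 when lost). Of these, TYMS (0.0893) and IRF7 (0.0543) did not pass with library totals, TYMS, E2F2, ATM and IRF7 without siCHRNA5+siTP53 replicate 1 or 2, and PARP9 without siCHRNA5+siTP53 replicate 2.

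The comparison of siCHRNA5+siTP53 with siControl measures the double treatment. It joined large falls of siTP53 with those of siCHRNA5. SLC5A8 fell by 8.22 ± 0.636 (adjusted p = 0.000172), to 0.0291 and 0.345 CPM, and SGCG (-6.52 ± 0.279, adjusted p = 3.22e-05) and METTL7A (-3.99 ± 0.256, adjusted p = 9.92e-05) fell as well. IFITM10 (-3.74 ± 0.333, adjusted p = 0.000225), the BMP antagonist gene CHRD (-3.69 ± 0.777, adjusted p = 0.00928) and the carboxylase gene ACACB (-3.62 ± 0.44, adjusted p = 0.000867) came next. TGFB2 (5.08 ± 0.705, adjusted p = 0.00154), CLDN1 (4.24 ± 0.342, adjusted p = 0.000179), AGR2 (4.23 ± 0.405, adjusted p = 0.000306) and ANXA3 (3.61 ± 0.456, adjusted p = 0.00102) rose most. So did the features with near-identical copies, AKR1C1 (4.00 ± 1.06, adjusted p = 0.0229) and MIR3648-2 (3.58 ± 0.68, adjusted p = 0.00598). In all 3897 genes (26.9%) passed by edgeR's test, 1758 higher and 2139 lower, or 1049 and 2735 with library totals, which moved the median of all genes by -0.13. The count was 1586 and 1451 without siControl replicate 1 or 2, 1101 and 1238 without siCHRNA5+siTP53 replicate 1 or 2, and 6652 and 6658 without siCHRNA5 replicate 1 or 2. MIR3648-2 did not pass without siControl replicate 2 (0.0705). CHRD did not pass without siControl replicate 1 or siCHRNA5+siTP53 replicate 1 or 2 (highest 0.087) nor with limma-voom (0.0556). AKR1C1 did not pass without any one siControl, siTP53 or siCHRNA5+siTP53 library (0.0507 to 0.157), nor with limma-voom (0.0754).

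Of the p53 targets, 17 fell and 3 rose in the double treatment against siControl (18 and 3 adjusted over the list alone). Their median was -0.661 (camera adjusted p = 0.000459, adjusted p = 0.616 with an estimated correlation), and the list did not pass over members without a siRNA heptamer (0.103). MDM2 (-1.47 ± 0.127, adjusted p = 0.000216) and BTG2 (-2.27 ± 0.216, adjusted p = 0.000295) fell. G2/M genes rose as a list by camera but not by fry (adjusted p = 0.295), with 6 up and 2 down of 40 (5 and 2 adjusted over the list alone). Their median was 0.248 (camera adjusted p = 0.0264, adjusted p = 0.781 with an estimated correlation), or 0.118 with library totals. The list did not pass without siControl replicate 1 (0.0646) or over members without a heptamer (0.0624), and 17 members rose without siCHRNA5 replicate 1 or without siCHRNA5 replicate 2. CDC20 (0.89 ± 0.102, adjusted p = 0.000682) and CCNB1 (0.78 ± 0.105, adjusted p = 0.00139) rose. G1/S genes did not pass as a list (0 up by edgeR and by DESeq2, 5 down of 39, 0 and 3 adjusted over the list alone, camera adjusted p = 0.13), but had 3 up and 9 down without siCHRNA5 replicate 1 or without siCHRNA5 replicate 2. Stress response genes rose, with 11 up and 3 down of 30 (12 and 4 adjusted over the list alone). Their median was 0.493 (camera adjusted p = 0.00311, adjusted p = 0.616 with an estimated correlation). Without siCHRNA5 replicate 1 or without siCHRNA5 replicate 2, 17 rose. The chaperone gene HSPA5 rose by 0.90 ± 0.116 (adjusted p = 0.00111) and PDIA6, 29.7% overlapped by the antisense gene ATP6V1C2, by 0.75 ± 0.108 (adjusted p = 0.00176). Replication histones rose, with 7 up and 0 down of 14 (9 and 0 adjusted over the list alone), by a median of 1.15 (camera adjusted p = 0.000325, adjusted p = 0.616 with an estimated correlation). Among lists that did not pass, ITGA5 (3.52 ± 0.27, adjusted p = 0.000162) and the hypoxia gene ADM (4.08 ± 0.455, adjusted p = 0.000596) rose. BCL2 (-2.04 ± 0.165, adjusted p = 0.000179), the fatty acid elongase gene ELOVL2 (-2.13 ± 0.285, adjusted p = 0.00128) and the RNA sensor gene IFIH1 (-1.84 ± 0.224, adjusted p = 0.000878), which holds a TP53 siRNA heptamer, fell.

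The comparison of siCHRNA5+siTP53 with siCHRNA5 asks what TP53 siRNA does in cells that already received CHRNA5 siRNA. It shares the siCHRNA5 libraries, with opposite sign, with the comparison of siCHRNA5 and siControl, so opposite movement in these 2 comparisons is in part built in and was not tested. CDKN1A fell by 5.73 ± 0.248 (adjusted p = 3.6e-05), SLC5A8 by 5.46 ± 0.632 (adjusted p = 0.000635), and SGCG by 4.90 ± 0.275 (adjusted p = 5.85e-05). IQCN fell by 4.33 ± 0.489 (adjusted p = 0.00058) and TP53INP1, a p53 target that holds heptamers of both siRNAs, by 4.58 ± 0.406 (adjusted p = 0.000248). HMOX1 fell by 4.33 ± 0.978 (adjusted p = 0.0117), or by 1.32 without siCHRNA5 replicate 1. Without siCHRNA5+siTP53 replicate 1 or 2 its value was -4.62 and -4.08 and it did not pass (adjusted p = 0.0745 and 0.0944). FOXI1 (4.34 ± 0.442, adjusted p = 0.000411), the membrane protein gene TM4SF1 (3.41 ± 0.348, adjusted p = 0.000412), and AGR2 (3.31 ± 0.383, adjusted p = 0.000635) rose most. CRAT (3.01 ± 0.466, adjusted p = 0.00219), the keratin gene KRT15 (2.98 ± 0.252, adjusted p = 0.000218) and RAB27B (2.91 ± 0.33, adjusted p = 0.000594) came next. In all 4056 genes (28%) passed, 1998 higher and 2058 lower, or 1383 and 2569 with library totals, which moved the median of all genes by -0.102. The count was 1342 and 1359 without siCHRNA5+siTP53 replicate 1 or 2, 6407 without siCHRNA5 replicate 2, and 1848 with only these 2 groups in the fit. CHRNA5 (1.28 ± 0.562, adjusted p = 0.119) did not pass with edgeR, but did with DESeq2 (0.0309) and without siCHRNA5 replicate 2 (9e-04).

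Of the p53 targets, 32 of 40 fell and 1 rose in siCHRNA5+siTP53 against siCHRNA5 (34 and 1 adjusted over the list alone). Their median was -2.04 (camera adjusted p = 6.46e-20, adjusted p = 0.271 with an estimated correlation), with RPS27L at -3.08 ± 0.161 (adjusted p = 5.85e-05) and FAS at -4.19 ± 0.262 (adjusted p = 7.18e-05). G1/S genes rose, with 34 up and 0 down of 39 (35 and 0 adjusted over the list alone). Their median was 0.971 (camera adjusted p = 2.92e-17, adjusted p = 0.355 with an estimated correlation). MCM7 rose by 1.04 ± 0.108 (adjusted p = 0.000443) and MCM5 by 1.12 ± 0.126 (adjusted p = 0.000564). G2/M genes rose, with 37 up and 1 down of 40 (38 and 1 adjusted over the list alone). Their median was 1.02 (camera adjusted p = 1.59e-16, adjusted p = 0.355 with an estimated correlation), with PLK1 at 1.18 ± 0.106 (adjusted p = 0.000262). DNA repair genes rose, with 23 up and 2 down of 39 (25 and 2 adjusted over the list alone), by a median of 0.742 (camera adjusted p = 5.76e-07, adjusted p = 0.374 with an estimated correlation).

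Hypoxia and glycolysis genes rose in siCHRNA5+siTP53 against siCHRNA5, with 11 up and 1 down of 26 (14 and 2 adjusted over the list alone, and 6 up with library totals). Their median was 0.411 (camera adjusted p = 0.000777, adjusted p = 0.355 with an estimated correlation), and NDRG1 rose by 1.69 ± 0.209 (adjusted p = 0.000826). Luminal genes rose, with 7 up and 1 down of 20 (8 and 1 adjusted over the list alone). Their median was 0.193 (camera adjusted p = 0.0133, adjusted p = 0.355 with an estimated correlation), or 0.0949 with library totals, and the list did not pass without siCHRNA5 replicate 2 (0.0916). The claudin gene CLDN7 rose by 1.30 ± 0.132 (adjusted p = 0.00041). Replication histones rose, with 6 up and 0 down of 14 (the same adjusted over the list alone). Their median was 0.822 (camera adjusted p = 0.00192, adjusted p = 0.374 with an estimated correlation). Lysosome genes fell, with 0 up by edgeR and by DESeq2 and 12 down of 29 (the same adjusted over the list alone). Their median was -0.413 (camera adjusted p = 0.00119, adjusted p = 0.515 with an estimated correlation), -0.265 without siCHRNA5 replicate 1, where the list did not pass (0.0817), and -0.753 without siCHRNA5 replicate 2. Without these libraries 5 rose and 8 fell, and 1 rose and 17 fell. By fry the lysosome list did not pass (adjusted p = 0.0799). GAA fell by 1.12 ± 0.11 (adjusted p = 0.000369). Estrogen response genes went both ways, with 7 up and 9 down of 36 (10 and 9 adjusted over the list alone), or 14 and 8 without siCHRNA5 replicate 1, 12 and 11 without siCHRNA5 replicate 2, and 3 and 9 with library totals. Their median was 0.162 and their mean -0.0205 (camera adjusted p = 0.837).

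The effects of TP53 siRNA without and with CHRNA5 siRNA, which share no library, correlated across genes at r = 0.623 (single-library values 0.483 to 0.569). They shared 642 rises where independent lists would share 128 and 894 falls where they would share 174, and 96.8% of the genes called with siTP53 alone had the same sign. The comparisons against siControl share their control libraries. For siCHRNA5 and siTP53, r across genes was 0.225 where simulated unchanged groups gave 0.49, the covariance was 0.155 against a simulated 0.0988, and 166 rises and 154 falls were shared where independent lists would share 57.7 and 104. Opposite calls numbered 84 and 114, against 76.1 and 79.1. For siTP53 and the double treatment r was 0.786 (simulated 0.48), the covariance 0.686 (simulated 0.0987), and 776 rises and 1018 falls were shared (independent lists 113 and 181). For siCHRNA5 and the double treatment r was 0.421 (simulated 0.48), the covariance 0.344 (simulated 0.0992), and 387 rises and 452 falls were shared (independent lists 109 and 182). Part of each excess may come from the shared controls, which 2 libraries do not allow to be split.

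Genes were also compared by the 7-base sequences in their 3' UTRs. Among 16158 heptamers in 9643 genes, the one tied to the lowest fold changes with siCHRNA5 was TGATATA (1157 genes, -0.32 log2, t = -18.32), followed by GATATAA (t = -17.5). These were also the 2 lowest with CHRNA5 siRNA on top of TP53 siRNA (t = -19.07 and -18.56), where the slope of TGATATA was -0.2 log2. Its interaction slope was 0.12 (t = 8.5, the highest of all heptamers), and its slope in siCHRNA5+siTP53 against siCHRNA5 was 0.12 (t = 5.6). Genes with this heptamer thus fell less with CHRNA5 siRNA in the double treatment, whose division of the siRNA dose is not stated, and the interaction does not separate this from dependence on TP53. With siTP53 it was GAGTGGA (1164 genes, -0.24 log2, t = -14.8), followed by AGTGGAA, and GAGTGGA was again lowest with TP53 siRNA on top of CHRNA5 siRNA (t = -12.91). TGATATA had t = 0.2 with siTP53 and GAGTGGA t = 0.7 with siCHRNA5. One of the first pair (here the CHRNA5 siRNA heptamers) was present in 34.2% of the genes that fell with siCHRNA5, 11.1% of those that rose and 14.9% of those that did not pass. With CHRNA5 siRNA on top of TP53 siRNA it was present in 54 of the 71 genes of the scan (76.1%) that fell. There it was present in 13.0% of those that rose and 16.2% of those that did not pass. One of the other pair (the TP53 siRNA heptamers) was present in 37.8% of the genes that fell with siTP53, 15.9% of those that rose and 21.7% of those that did not pass. Both pairs were chosen from the fold changes of siCHRNA5 and siTP53 against siControl, so their higher shares among those falls are in part built in. The shares cover only genes with at least 5 CPM and a 3' UTR sequence, and they are not adjusted for 3' UTR length. Calls in which no heptamer of the siRNA in question was found numbered 804 up and 853 down with siCHRNA5. They were 21 and 19 with CHRNA5 siRNA on top of TP53 siRNA, and 786 and 828 with siTP53. These counts cover all genes tested and include genes that had no 3' UTR sequence to search, so not all of them are known to lack a heptamer. Of genes named above and not yet marked, CHRNA5, IREB2, KITLG, PPM1D, PGR, SLC39A6, BCL2L1, TGFB2, MACC1, IL6ST, TMPRSS4, RAB27B, PARP9 and PSMA4 also hold a CHRNA5 siRNA heptamer, and TP53, DHFR, EGR1, LIF, MCL1, PGR, HSPA5, ATM, E2F2, CENPA, TM4SF1, RAB27B and PSMA4 a TP53 siRNA heptamer.

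**Figure D4:**
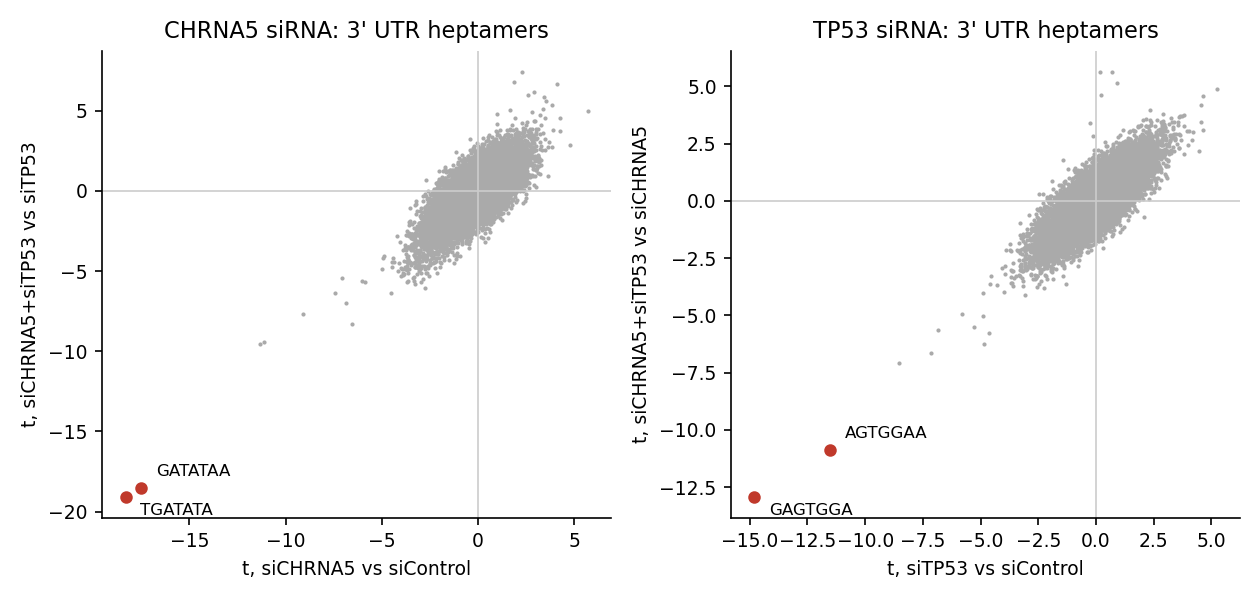
The t of each of 16158 heptamers for the link between its presence in 3' UTRs and the log2 fold change, with CHRNA5 siRNA alone and on top of TP53 siRNA (left) and with TP53 siRNA alone and on top of CHRNA5 siRNA (right). The red points are the 2 lowest heptamers of the first comparison, TGATATA at -18.32 and -19.07 on the left and GAGTGGA at -14.8 and -12.91 on the right.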

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

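The interaction, a test of whether CHRNA5 siRNA acts differently without and with TP53 siRNA, flagged 2 genes and 7 gene lists as differing between groups. The genes are CDKN1A (-3.53 on the log2 scale) and RPS27L (-2.06). The lists, by mean log2 interaction, are p53 targets (-1.3), G1/S replication genes (0.839), G2/M genes (0.715), DNA repair and checkpoint genes (0.564), hypoxia and glycolysis genes (0.129), lysosome and autophagy genes (-0.352) and immediate early genes (-0.853). No list keeps its call with an estimated correlation, and only p53 targets passed by fry (adjusted p = 0.0358). The last 3 lists also lose theirs when a single library is left out. Groups of 2 are too small for a test of single outlying libraries.

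The rise of p53 targets with CHRNA5 siRNA alone, while MDM2 did not rise, was weighed first, and its test of p53 activity was chosen after seeing the result. If p53 activity raised these genes, they should stay level when TP53 is silenced, and their median with CHRNA5 siRNA on top of TP53 siRNA was -0.0824. Single members ranged from -1.48 to 2.66 there, so the median does not show that each target stayed level. The choice between TMM and library totals made little difference, since the median with siCHRNA5 was 1.28 and 1.24. Library totals moved the median of all genes by only -0.0284, so they could not have removed the rise. An error common to both scalings was not tested. Without siCHRNA5 replicate 1 the median was 1.11, so that library alone does not account for the rise. Lower MDM2 RNA through a seed match of the CHRNA5 siRNA could raise p53 itself. With TP53 silenced MDM2 fell by 1.48 (-1.48) on CHRNA5 siRNA. The fall of MDM2 in the double treatment was of like size against siControl, so TP53 siRNA alone left its RNA nearly level. Its longest 3' UTR (10837 bases) holds 7 occurrences of TGATATA or GATATAA, which can overlap, so a site may be counted more than once. Of 106 genes with 3' UTRs of similar length, 63.2% hold either heptamer. Numbers of sites were not compared between genes, so whether MDM2 holds unusually many was not tested. A weaker action of the CHRNA5 siRNA in the double treatment (TGATATA slope -0.2 against -0.32) was not tested as a cause. Nor were other genes with a CHRNA5 siRNA heptamer (1605 genes, median -0.16 with siCHRNA5, against 0.05 in genes without one). The tests therefore leave open whether the p53 response comes from loss of CHRNA5, from MDM2 or from something else.

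The falls shared by both CHRNA5 siRNA comparisons were weighed second. In seed matches of one small RNA given with the CHRNA5 siRNA, the same heptamer should lead in comparisons that share no library, and TGATATA led in both (t = -19.07 in the comparison on top of TP53 siRNA). The base composition of 3' UTRs does not account for this, since the lowest t among 126 heptamers of the same composition was -3.28. If the small RNA is the guide strand of an siRNA against CHRNA5, the heptamer should lie in CHRNA5, and it was in 1 of 2 annotated transcripts, against 17.6% of genes, which is weak evidence. With a single siRNA treatment, the labels giving neither sequence nor number, falls through such matches and falls through loss of CHRNA5 may both be present and could not be separated.

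The falls shared by both TP53 siRNA comparisons were weighed last. For seed matches of one small RNA given with the TP53 siRNA, GAGTGGA led in both comparisons (t = -12.91 on top of CHRNA5 siRNA). If the small RNA is the guide strand of an siRNA against TP53, the heptamer should lie in TP53. It was in 19 of 19 annotated transcripts, while 29.9% of genes held it in any transcript. Transcripts of a gene share sequence, so these are not 19 separate findings, and the evidence is weak here too. An endogenous small RNA with the same seed was not tested, and no second siRNA was at hand, so it could not be told which falls follow from loss of p53.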

How the results depend on the processing

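Leaving out a library leaves 1 sample in its group, which is assumed to vary like the other groups, and quality weights and lists without members holding a heptamer were added after seeing the data. No called gene changed direction under any alternative. Among the named genes compared, 1 value turned sign, that of TP53 in siCHRNA5 against siControl, which was 0.0534 without siCHRNA5 replicate 1 and -0.284 without replicate 2, and it never passed. List medians also turned sign, among them that of lysosome genes with siCHRNA5 (0.295, or -0.0468 without siCHRNA5 replicate 1). That of p53 targets with CHRNA5 siRNA on top of TP53 siRNA was -0.0824, or 0.0489 without siCHRNA5+siTP53 replicate 2. Apart from the counts below, leaving out a library kept the call or its absence in 1161 gene values, ended 194 and added 4, and in lists kept 258 and ended 14. The other alternatives kept 1007 gene values, ended 12 and added 1, and in lists kept 113 and ended 57, of which 34 with an estimated correlation, which left 0 of the 34 list calls. Fry kept 15 of the 34 and called 23 lists in all, and leaving out a library gave 33 to 45 calls. For siCHRNA5 against siControl (2134 genes), leaving out a library gave 477 to 4932, quality weights 1224, only the compared groups 342 and an adjusted p under 0.01 697. In the same order siTP53 against siControl (2155) gave 299 to 5213, 4393, 4438 and 593. The double treatment against siControl (3897) gave 1101 to 6658, 7473, 7361 and 1688, and against siTP53 (98) 0 to 1457, 1485, 1305 and 26, with 481 by DESeq2. The double treatment against siCHRNA5 (4056) gave 1342 to 6407, 1848 with only the compared groups and 1852 under 0.01. The interaction (2) gave 0 to 1864 without a library, 12 with library totals, 351 with DESeq2, 68 with quality weights, and 0 under 0.01. Shared spread explains part of this by construction. The siCHRNA5 libraries, with weights 0.301 and 0.303 against 2.58 and 2.65 for the double treatment, raise it for every comparison, and counts in comparisons without them rose when one was left out. Beyond that the cause was not tested. The correlation of the CHRNA5 siRNA fold changes (0.374) was 0.267 without the filter, 0.617 with the filter at 5 CPM and 0.224 to 0.317 without a library. In simulations of siCHRNA5 against siControl, planted changes of 1 on the log2 scale were found in 55% of cases. No changes were planted for other comparisons. An absent call is therefore not evidence of no change.

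The labels do not pair the libraries. Deviations from the group mean correlated between groups at -0.072 to 0.28, no pair of groups below -0.1, with only 2 pairs each. The replicate number as a block left 1 gene with an interaction and 70 genes in the double treatment against siTP53. It ended the calls of AKR1C1 in siCHRNA5 against siControl (adjusted p = 0.0681), of USP2 (0.0703) and ARID3B (0.0673) in the double treatment against siTP53, and of RPS27L in the interaction (0.0703).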

Other observations

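Markers of other cell types were looked at one by one, since their lists had no call or were not tested. ACTA2, a basal epithelial marker here, which encodes smooth muscle actin and overlaps an antisense gene over 38.3% of its exonic bases, was at 1.13 and 1.08 CPM in siControl and 13.8 and 11.4 CPM in siCHRNA5 (log2 3.51 ± 0.435, edgeR adjusted p = 0.00187). It fell with siTP53 (-3.06 ± 0.565, adjusted p = 0.0102, but 0.0639 and 0.0699 without siControl replicate 1 or 2, and -5.19 without siTP53 replicate 1). The collagen gene COL1A1, a fibroblast marker that MCF7 cells express here, was at 23.3 and 23.7 CPM in siControl, 33.9 and 40.3 CPM in siCHRNA5, 9.88 and 9.44 CPM in siTP53 and 10.7 and 12.1 CPM in the double treatment. It fell with siTP53 (-1.28 ± 0.152, adjusted p = 0.00194) and in the double treatment against siCHRNA5 (-1.71 ± 0.153, adjusted p = 0.000258). Its rise with siCHRNA5 (0.66 ± 0.148, adjusted p = 0.0196) did not pass without siControl replicate 1 or 2 (0.126 to 0.133). COL1A1 holds a TP53 siRNA heptamer.

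Further list members passed in the double treatment against siControl. RRM1 of nucleotide synthesis (-0.77, adjusted p = 0.00619), the ligase gene LIG1 (-0.96, adjusted p = 0.00842) and FANCE (-0.90, adjusted p = 0.00749) fell. Without siControl replicate 2 or siCHRNA5+siTP53 replicate 1 or 2 they did not pass (adjusted p up to 0.0809), with values of -0.72 to -0.80 for RRM1, -0.87 to -0.98 for LIG1 and -0.77 to -0.93 for FANCE. The cytochrome c gene CYCS rose (0.94, adjusted p = 0.00102). Against siCHRNA5, the apoptosis gene BBC3, a p53 target (-2.62, adjusted p = 0.000413), SESN2 (-2.31, adjusted p = 0.000124), BTG2 (-3.75, adjusted p = 7.09e-05) and the receptor subunit gene CHRNB1 (-0.996, adjusted p = 0.0206, but 0.173 without siCHRNA5+siTP53 replicate 1) fell, and FANCD2 (1.40, adjusted p = 0.000248), IL6ST (1.96, adjusted p = 9.22e-05) and XBP1 (1.46, adjusted p = 0.000289) rose.

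Of 21 lists tested in 6 comparisons, 13 had a camera call in at least 1 comparison and 8 had none. The lowest camera adjusted p of those 8 over the comparisons was 0.129 for estrogen response, 0.0845 for apoptosis, 0.075 for nicotinic receptors, 0.448 for cholesterol synthesis, 0.0626 for mitochondrially encoded genes, 0.109 for basal epithelial markers, 0.305 for leukocyte markers and 0.0756 for endothelial markers. Median, mean and test did not share a sign for nicotinic receptors with siTP53 (-0.0588, -0.126, camera up), endothelial markers with siTP53 (0.0635 and -0.366), basal markers in the double treatment against siCHRNA5 (0.511 and -0.259) and mesenchymal genes in the interaction (-0.26 and 0.276). Fibroblast markers were not tested as a list. Leukocyte and endothelial markers were low in all libraries, for example CD8A at 0.383 to 1.4 CPM and EMCN at 1.63 to 3.49 CPM. The endothelial marker VWF passed as higher in the double treatment (3.75 and 3.93 CPM) than in siCHRNA5 (0.702 and 1.36 CPM). It did not pass without siCHRNA5+siTP53 replicate 1 or 2. Mitochondrially encoded mRNA made up 1.2% and 1.91% of the reads in siControl, 1.45% and 2.2% in siCHRNA5, 1.66% and 1.54% in siTP53, and 1.64% and 1.87% in the double treatment, and ND6, whose gene lies opposite others on the same molecule so that the unstated strand setting leaves its counts uncertain, rose with siCHRNA5 (1.01 ± 0.227, adjusted p = 0.0194, but 0.129 without siControl replicate 1).

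The first principal component held 55.2% of the variance, the next 25.9% and the third 9.69%, on which the siCHRNA5 libraries lay at -17.2 and 28.8. The 10 most highly expressed genes took 5.67% to 7.42% of the reads of a library.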
